A study of Homo sapiens with 16 samples.

How the data were processed

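The samples were 16 Caco-2 xenograft tumours, 8 control and 8 of the galectin-9 group, with groups and replicate numbers taken from sample titles and characteristics. Per the labels, RNA was labelled with Cy5 for Toray 3D-Gene miRNA arrays. The labels disagree on the material: titles and characteristics name xenograft tumours, while the extraction text speaks of serum and the treatment text of cultured cells. The samples are described here as tumours, as their titles say.

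Per the file headers, the authors' scanner files hold linear spot intensity, foreground and local background, not normalized, in 1 channel that the header calls 532. No spot was flagged. The deposited table of the whole series holds intensity that, from its values, follows the scanner's foreground means in rank and has the same distribution on every array, with no background subtracted. Its column medians were 229.9 or 230 on every array. Its scale is linear, but the arrays that set its common distribution are unknown, and the authors' software is not given in the sources used here. It served as an alternative.

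Foreground medians were corrected with normexp (offset 50) on all 3200 spots, and the 2019 miRNA probes were quantile normalized and put on log2 scale. A probe counted as detected above the mean plus 2 SD of the array's 925 BLANK spots, after trimming 5% at each end. Probes detected on at least 8 arrays, 936 (46.4%), were tested with limma (lmFit and eBayes) for galectin-9 minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Probe names are those of the files, and 15 probes name several miRNAs. Gene neighbours came from a RefSeq table of assembly GRCh38.p14.

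There were 18 miRNA lists, on the miR-200 family, intestinal epithelium, miR-17-92, let-7, p53, colorectal cancer, miR-15 and miR-16 with miR-29, miR-26 and miR-101, miR-30, fibroblasts and smooth muscle, skeletal muscle, endothelium, leukocytes, erythroid cells, liver and brain, hypoxia, the DLK1-DIO3 cluster, C19MC and numbers of 3000 or above. The 16 lists with at least 3 tested members were tested with camera (preset correlation 0.01), and again with an estimated correlation, with fry and with an exact permutation test of list means over all 12870 assignments of the arrays. Detection was compared with Fisher's exact test.

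The named miRNAs were the 10 largest rises and 10 largest falls past the threshold, filled up to 20 by unadjusted p where fewer passed, the 5 brightest probes, and up to 3 members of highest mean per list. These lists, rules and tests were fixed before the data were examined. miR-205-5p was named after its values were seen.

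The fit was tested on simulated data for this comparison, 936 probes with 200 changed. It recovered 47 of 67 probes changed 1.5-fold, 65 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 9 false calls. With 200 of 936 changed the adjustment is milder than with few changes. These counts therefore do not give the recovery where only a few miRNAs change. The changes were added in full to normalized log2 values. A true change of a dim probe would be shrunk by the offset, so recovery for dim probes is overstated. On 500 simulated sets with no change, camera with the preset correlation called a list in 26. These simulated probes varied independently, which real probes do not.

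Alternatives covered background, foreground statistic, scaling, detection filter, variance model, array weights, permutation, a replicate block and each array left out. Chosen after seeing the data were the limit from No Probe spots, the presumed chip as a block, the cell of the chip as a random block, the mean of miR-203a and miR-205-5p as a covariate, the fit without 7 arrays, and the intestinal list without miR-203a. Controls lay in cells 1 and 3 of each presumed chip and galectin-9 arrays in cells 2 and 4, so no cell held both groups. R 4.3.3 and limma 3.58.1 were used, and matplotlib 3.10.9 for plots.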

Results

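Caco-2 is an established human colon cancer cell line with features of intestinal epithelium, grown here as xenograft tumours. Galectin-9 is a lectin that binds beta-galactoside sugars. The series asked how galectin-9 acts on colon cancer growth, and this part of it measured microRNAs (miRNAs) in Caco-2 xenograft tumours. There were 16 arrays, 8 from control tumours and 8 from tumours of the galectin-9 group, for which the labels give a dose of 30 µg. Each array held 3200 spots, of which 2019 were probes for human miRNAs. Control arrays detected 1001.5 ± 80.8 miRNA probes and galectin-9 arrays 1005.5 ± 184 (mean ± SD, n = 8 each; exact two-sided permutation test, p = 0.960), and single arrays ranged from 742 to 1357. On all 16 arrays 368 probes were detected, on none 71, and the 936 probes detected on at least 8 arrays were tested. The labels do not say that each tumour came from its own animal, so p-values measure the spread between these samples. The number of arrays limits the precision.

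No single miRNA passed the test between galectin-9 and control tumours, given the spread between arrays of a group. Among the 20 miRNAs with the lowest p were 2 of intestinal epithelium, miR-194-5p and miR-192-5p, and the probe for miR-199a-3p and miR-199b-3p, which are abundant in fibroblasts. All of these had lower means with galectin-9, and miR-1246 had a higher one. The miR-194-5p value was 7.72 ± 0.61 on log2 scale with galectin-9 and 8.65 ± 0.85 in control (mean ± SD, n = 8 each), a difference of -0.94 ± 0.33 (SE) with a limma adjusted p of 0.940. For miR-192-5p the difference was -0.86 ± 0.34 (SE), for miR-199a-3p and miR-199b-3p -0.81 ± 0.28, and for miR-1246 0.86 ± 0.29, each with the same adjusted p. Smaller differences among the 20 lowest p were those of miR-520d-5p (-0.40), miR-152 (-0.45), miR-378d (-0.37), miR-378f (-0.37), miR-185-5p (-0.28), miR-20a-3p (-0.32), miR-6511a-5p (0.42) and miR-365b-5p (0.31), none past the test. The lowest p of all were those of miR-520d-5p, miR-365b-5p and miR-6511a-5p, all dim. Their probes were detected on 8, 2 and 2 control arrays and on 4, 6 and 7 galectin-9 arrays.

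In limma, 0 miRNAs passed an adjusted p of 0.05 in either direction, and 35 had an unadjusted p under 0.05 (15 higher, 20 lower), where chance alone gives 46.8 of 936. The exact permutation test of each probe also gave 0, with 36 at an unadjusted p under 0.05. Its smallest possible p is 0.000155, so a single probe could not pass it over 936. No cell of the chip held both groups, and with the cell as a random block limma gave 0, with 40 at an unadjusted p under 0.05. The 95% interval of the difference lay within 2-fold in both directions for 885 of the 936 miRNAs (94.6%) and within 1.5-fold for 759 (81.1%). The largest difference, that of miR-203a, was -1.74 with an interval from -4.13 to 0.64. The 5 brightest probes were those of miR-4454, miR-5100, miR-3960, miR-1260b and miR-4286, with differences of -0.13, -0.25, 0.25, -0.27 and -0.08. Without galectin-9 replicate 4, those of miR-5100, miR-3960, miR-1260b and miR-4286 were -0.02, 0.01, -0.06 and 0.13. One miRNA spot per array was at the scanner's ceiling, that of miR-4454 on 15 arrays, so its difference is bounded by saturation.

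**Figure D1:**
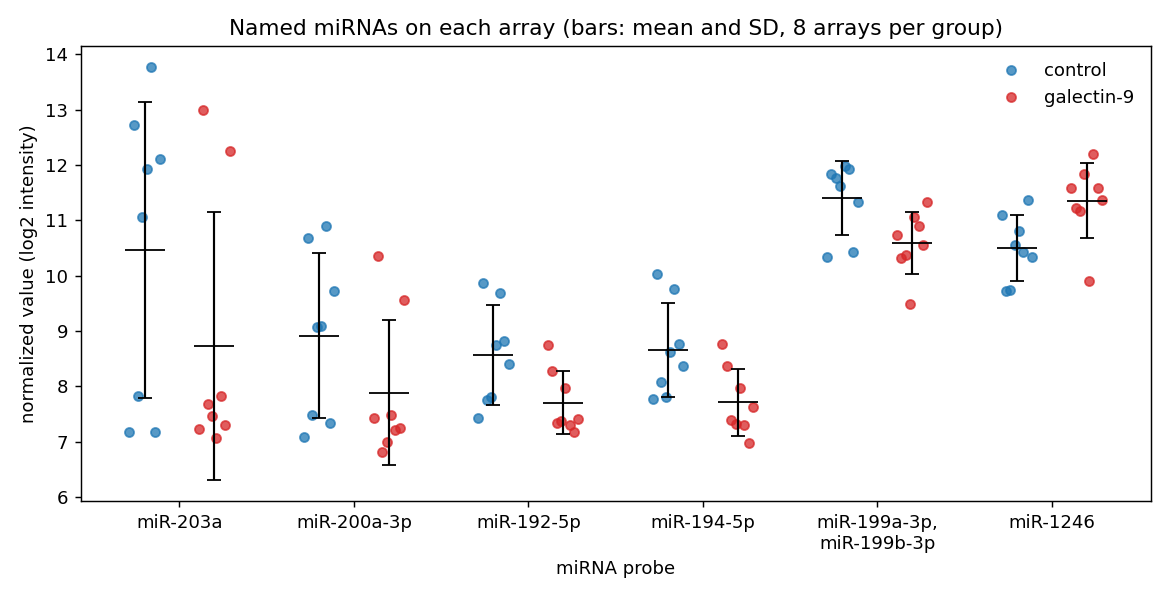
Normalized log2 intensity (vertical axis) of 6 miRNA probes (horizontal axis) on each of the 8 control and 8 galectin-9 arrays, with points for arrays and bars for the mean and SD. The groups overlap for every probe shown, and miR-203a lies either between 7.06 and 7.83 or between 11.1 and 13.8.

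Epithelial miRNAs had lower means with galectin-9 but varied widely between tumours of the same group. The 4 tested members of the miR-200 family, which maintains the epithelial state, all had lower means: miR-200a-3p by -1.03, miR-200c-3p by -0.88 and miR-200b-3p by -0.69. Of the 8 tested miRNAs of intestinal epithelium all 8 had lower means, 2 of them at an unadjusted p under 0.05. The family's mean value was 7.62 ± 0.97 with galectin-9 and 8.44 ± 1.16 in control, a difference of -0.83, and the intestinal list's was 7.38 ± 0.39 and 7.90 ± 0.56, a difference of -0.52 (mean ± SD, n = 8 each). The intestinal list's median member differed by -0.19, and without miR-203a, a setting chosen after seeing the data, the list's mean differed by -0.35 (camera adjusted p = 0.00137, and adjusted p = 0.159 with an estimated correlation). Set against the other tested miRNAs by camera with a preset correlation, both lists were lower (adjusted p = 0.00224 and 0.000449). With an estimated correlation neither call held (adjusted p = 0.306 and 0.159). Further settings were chosen after seeing the data. With the detection limit from No Probe spots the intestinal list differed by -1.18 (camera adjusted p = 0.00099), over fewer members, so this value does not compare with -0.52. With the mean of miR-203a and miR-205-5p as a covariate it differed by -0.21 (camera adjusted p = 0.0504, no longer called). As miR-203a is in this list, the covariate removes part of the difference by construction. The miR-200 family differed by -0.09 with the covariate (camera adjusted p = 0.428). Without the 7 arrays bright for miR-203a it differed by -0.13 (camera adjusted p = 0.343). The high values of the miR-200 family stood on the 7 arrays that were also bright for miR-203a, 5 control and 2 galectin-9 arrays. The family's mean was 8.33 to 10.14 on these 7 arrays and only 6.93 to 7.46 on the others. Each group mean therefore averages over bright and dim arrays and does not show a graded shift.

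The lists of fibroblasts and smooth muscle, leukocytes and skeletal muscle were also lower by camera with a preset correlation, and the erythroid list was not called. All 10 tested miRNAs of fibroblasts and smooth muscle had lower means, a mean difference of -0.32 (camera adjusted p = 1.83e-05, and adjusted p = 0.159 with an estimated correlation), with miR-199a-5p at -0.57, miR-143-3p at -0.35 and miR-10b-5p at -0.15. Without galectin-9 replicate 4, miR-143-3p was at -0.21 and miR-10b-5p at 0.03. All 7 leukocyte miRNAs had lower means, a mean difference of -0.26 (0.00219, and adjusted p = 0.306 with an estimated correlation), with miR-223-3p of myeloid cells at -0.52, miR-146a-5p at -0.32 and miR-342-3p at -0.25. The leukocyte difference was -0.17 without control replicate 6, and miR-146a-5p was at -0.20 without galectin-9 replicate 4. The 4 skeletal muscle miRNAs, whose mean was highest on the same 7 arrays as miR-203a, differed by -0.32 (0.0238, and adjusted p = 0.466 with an estimated correlation), with miR-133b at -0.44 and miR-1 at -0.27. The skeletal muscle call held in 7 of 16 fits with one array left out, and miR-133b was at -0.67 without galectin-9 replicate 2. Both endothelial probes had lower means (miR-126-3p by -0.43), too few for the list test (exact permutation p = 0.0813 for their mean). The erythroid list differed by -0.17 (camera adjusted p = 0.392), with miR-451a at -0.43 and miR-144-3p at 0.06. Without control replicate 6 the erythroid list differed by -0.07 and miR-451a by -0.13, and without galectin-9 replicate 6 by -0.29 and -0.76.

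Among growth-related miRNAs, those induced by the tumour suppressor p53 differed by -0.24 and those of the miR-17-92 cluster and its paralogs by -0.15. In the p53 list 10 of 11 tested members had lower means (camera adjusted p = 0.00206, and adjusted p = 0.192 with an estimated correlation). Its brightest member, miR-107, differed by -0.02 (0.09 without galectin-9 replicate 4). Another lower member, miR-34b-3p (-0.25), was dim and detected on only 7 control and 3 galectin-9 arrays. The only higher member of the list was miR-1246. Of its 11 tested members the p53 list shares 3 with the intestinal list (miR-192-5p, miR-194-5p and miR-215). It shares 2 with the list of fibroblasts and smooth muscle (miR-143-3p and miR-145-5p). In the miR-17-92 list 14 of 15 had lower means (0.00587, and adjusted p = 0.554 with an estimated correlation), with miR-17-5p at -0.15. The let-7 family differed by -0.22 (camera adjusted p = 0.0617), with let-7c at -0.63 and let-7a-5p at 0.05. The miR-30 family differed by -0.16 (0.0971). The list of miR-15, miR-16, miR-29, miR-26 and miR-101 differed by -0.12 (0.320), with a median member difference of -0.002. These values rested largely on galectin-9 replicate 4: without it the let-7 family differed by -0.04, the miR-30 family by -0.04, the miR-17-92 list by -0.06 (camera adjusted p = 0.267) and the list of miR-15, miR-16, miR-29, miR-26 and miR-101 by 0.04, with miR-17-5p at 0.003 and let-7a-5p at 0.32.

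MiRNAs often raised in colorectal cancer were not called as a list (difference -0.03, camera adjusted p = 0.537), with miR-21-5p at 0.10, miR-31-5p at 0.11 and miR-221-3p at 0.07. Without galectin-9 replicate 4 the list differed by 0.03, miR-21-5p by 0.29 and miR-31-5p by 0.25. The hypoxia-induced miR-210 differed by 0.05 with an interval from -0.26 to 0.36. The imprinted DLK1-DIO3 cluster was higher by 0.07 on average, 29 of 35 members with higher means (camera adjusted p = 0.0498, and adjusted p = 0.572 with an estimated correlation). Of its brightest members, miR-376c-3p was at 0.26 (0.13 without galectin-9 replicate 8) and miR-494 at 0.15 (0.38 without galectin-9 replicate 6). The third, miR-379-5p, was lower at -0.22 (-0.11 without control replicate 3). The cluster's call held in 9 of 16 fits with one array left out, with differences from 0.005 without galectin-9 replicate 5 to 0.11 without control replicate 3. It held in 10 of 19 other settings of camera with the preset correlation. Of 317 tested miRNAs numbered 3000 or above, 219 had higher means, a mean difference of 0.09 (1.56e-06, and adjusted p = 0.306 with an estimated correlation), or 0.05 without galectin-9 replicate 4. C19MC, a placental cluster, differed by -0.03 (0.313), and liver and brain miRNAs by -0.002 (0.920), where miR-9-5p differed by 0.05.

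Over the 16 lists tested, camera with a preset correlation called 7 lower and 2 higher. With an estimated correlation, with fry and with the exact permutation test of each list's mean it was 0, the lowest adjusted p being 0.159, 0.230 and 0.384. Of 69 named miRNAs, none of which passed, 37 had a difference that moved by over 1.5 times with one array left out, and 18 of these changed sign. Adjusted over the list alone, 0 members of any list passed, as over all miRNAs. Without the 7 arrays bright for miR-203a, 2 lists were called lower (fibroblasts and smooth muscle, and p53) and 1 higher (numbered 3000 or above), from 3 control and 6 galectin-9 arrays.

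**Figure D2:**
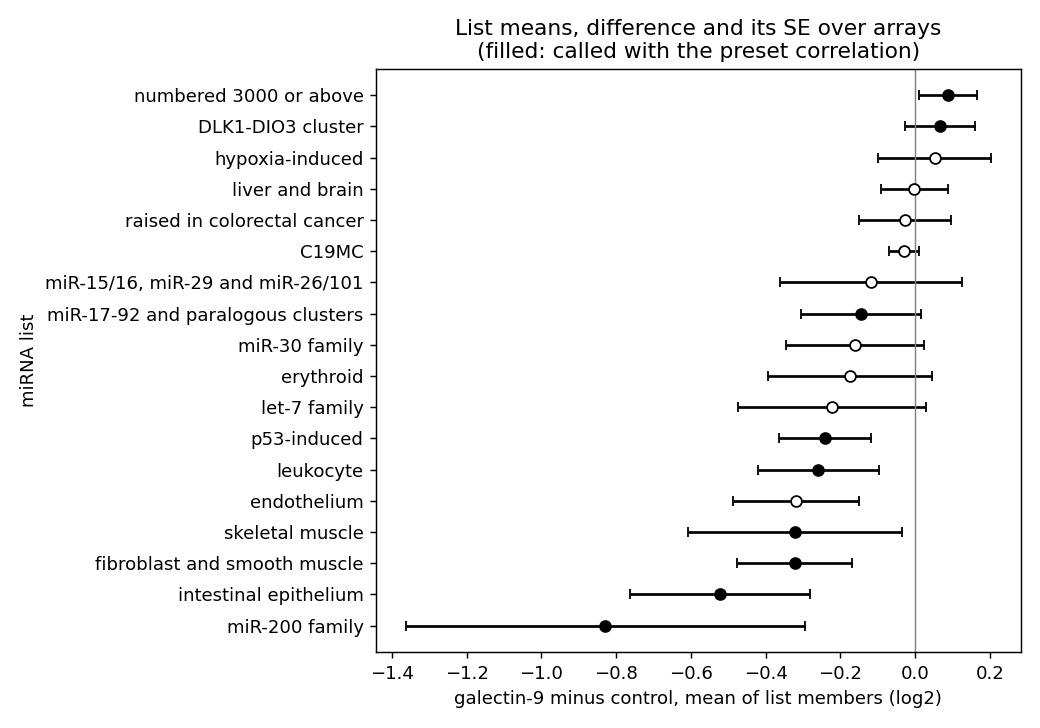
Difference between galectin-9 and control arrays in the mean log2 value of each miRNA list (horizontal axis), with the lists on the vertical axis and bars for the SE over 8 arrays per group. Filled points are the lists called by camera with a preset correlation, 7 lower and 2 higher, and the miR-200 family has the lowest value, -0.83.

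No probe was detected on all arrays of one group and on 0 of the other. Of 1580 probes detected on some but not all arrays, 0 passed Fisher's exact test after adjustment and 11 had an unadjusted p under 0.05. The smallest p this test can give here is 0.000155, so a single probe could not pass over 1580. The count of 0 therefore does not show equal detection. The lowest p was 0.00699, for miR-15b-3p, detected on 8 control and 2 galectin-9 arrays.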

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

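Of the tests in this part, the counts over other splits were set before their results were seen, and the tests of skin, cell, treatment and covariate were chosen after.

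Over 176 groups of 8 arrays, 15 had an array far from the rest, where chance gives about 1 in 20, or 8.8. Of these, 9 lay on galectin-9 replicate 4, the lowest of its group for miR-4454 (14.93), miR-5100 (12.94), miR-1260b (12.60), miR-4286 (11.80), miR-17-5p (9.81), let-7a-5p (11.05), let-7d-5p (10.21), miR-199a-5p (8.44) and the let-7 family mean (9.49). This array also detected the most probes, 1357. Its 9 values come from 1 array and are not independent, so 15 does not compare directly with 8.8. For miR-4454 the other arrays of the group were all at the scanner's ceiling. Control replicate 3 was highest for miR-520d-5p (8.03) and miR-34b-3p (7.44) and lowest for miR-9-3p (6.95). Control replicate 1 was lowest for miR-30c-5p (8.86). Galectin-9 replicate 5 was lowest for miR-1246 (9.90), and galectin-9 replicate 6 for miR-494 (7.85).

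On 7 arrays, control replicates 2, 4, 5, 6 and 8 and galectin-9 replicates 2 and 8, the mean of miR-203a and miR-205-5p was 10.91 or more, and on the other 9 it was 7.77 or less. The cell of the chip was not the whole cause, as 2 of 4 cells held arrays of both kinds, but cells 1 to 4 held 1, 0, 4 and 2 of the 7, so a part played by position stays open. Galectin-9 was not the whole cause either, as 5 arrays were out of place for a split by group. A candidate source is host skin and the muscle under it in the sampled tissue: all 7 arrays were also the 7 with the highest skeletal muscle mean, where chance gives 3.06. The array cannot tell host from human miRNAs of the same sequence, and differing amounts of Caco-2 cells stay open as a source.

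Chance could not be excluded for the 9 lists called by camera with a preset correlation. Of 100 splits of the 16 arrays, the real one included, 13 gave as many, the highest other giving 12. With the mean of miR-203a and miR-205-5p as a covariate 1 list, that of fibroblasts and smooth muscle, was called lower, and the leukocyte difference went from -0.26 to -0.08, so the calls may follow what varies with these miRNAs between tumours. This covariate partly follows the groups, so an effect of galectin-9 on these miRNAs stays open. For the intestinal list, which holds miR-203a, it also removes part of the difference by construction.

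Nor could chance be excluded for the 35 miRNAs at an unadjusted p under 0.05. Of the 100 splits, the real one included, 45 gave as many, and the highest other gave 178. For the count of 0 past the threshold the splits say nothing, since every split, 100 of 100, gives at least 0. Of the other splits 1 called any miRNA, 22 of them, and their median was 0; whether that split follows a structure of the samples was not tested.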

How the results depend on the processing

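The count of 0 miRNAs past the threshold held under all alternatives run. The count at an unadjusted p under 0.05 was 35 of 936, and 15 with median scaling. It was 82 of 2019 without a filter and 11 of the 368 probes detected on all 16 arrays. With one array left out it was 24 to 72 (61 and 72 without control replicates 1 and 7, 54 and 55 without galectin-9 replicates 2 and 8). In settings chosen after seeing the data it was 15 with the covariate and 18 without the 7 arrays. It was 11 with the No Probe limit, also chosen then, which tests a different set of probes. Counts over different numbers of probes do not compare directly. Lists called lower went from 7 to 0 with the exact permutation test, 0 with an estimated correlation (also for the intestinal list without miR-203a) and 0 with fry, to 1 with the covariate and 2 without the 7 arrays. Lists called higher went from 2 to 0 with those tests and with the covariate, and to 1 with the series table, plain subtraction, offset 16, foreground means, probes detected on all 16, the trended fit, the No Probe limit and without the 7 arrays, and were 1 to 2 with one array left out. The skeletal muscle difference turned to 0.061 with the covariate, and that of the DLK1-DIO3 cluster to -0.014 without the 7 arrays. The skeletal muscle mean was highest on the same 7 arrays as the covariate, so the covariate takes up much of this list's difference. The cause of the DLK1-DIO3 change was not tested. Of 69 named miRNAs 0 passed in any of 36 settings, and 29 changed sign in some. Replicate numbers did not pair the arrays (same-numbered correlations -0.16 to 0.63, not every array best with its own number). With the number as a block, 0 miRNAs passed, 49 had an unadjusted p under 0.05, and 9 lists were lower and 2 higher, as by presumed chip. Slide and scan date (not in the files) were not run. No scaling moved the median difference by over 0.1. The miR-17-92 call ended without control replicate 3 (-0.09) or galectin-9 replicate 4 (-0.06). The skeletal muscle call ended with the series table (-0.16), foreground means (-0.20), without control replicate 4, 5, 6 or 8 or galectin-9 replicate 1, 3, 4, 5 or 7, and the DLK1-DIO3 call without control replicate 1, 4, 5, 6 or 7 or galectin-9 replicate 5 or 8 (-0.48 to -0.24 and 0.005 to 0.11 over all arrays left out). The let-7 family was called lower without control replicate 1, 4 or 7 or galectin-9 replicate 1, 2 or 6, and the miR-30 family without control replicate 1 or galectin-9 replicate 2, 5 or 6. Signal over background limits dim probes.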

Other observations

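The relation in this part was chosen after the values were seen. miR-192-5p and miR-194-5p, both miRNAs of intestinal epithelium, moved together over the 16 arrays (Pearson r = 0.985, Spearman rho = 0.987, permutation p = 1e-05 for each, the smallest the resamples can give). Without the 2 arrays farthest from the median of miR-192-5p, r was 0.965, and within control and galectin-9 arrays it was 0.981 and 0.982. This was 1 relation tested. MIR192 and MIR194-2 are neighbours in the RefSeq table of assembly GRCh38.p14, as are MIR215 and MIR194-1. Neither joint transcription nor tumours differing in epithelial share was tested, and both predict this relation.

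Both miRNAs partly left the pattern of miR-203a: galectin-9 replicate 1 was at 8.75 for miR-192-5p with miR-203a at 7.22, and galectin-9 replicate 8 was at 7.41 with miR-203a at 12.25. The first principal component held 41.4% of the variance, and its difference between the groups did not pass (exact permutation p = 0.184).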
